A study of Mus musculus with 33 samples.

How the data were processed

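The series measured RNA of cell populations sorted from mouse bone marrow. Per the labels' protocols, RNA was extracted with PicoPure columns (median RIN 9.4), 2 ng of RNA with 1 ul of a 1:50000 dilution of ERCC spike-in RNA was reverse transcribed and amplified by SMARTSeq v2 with 20 uM template switching oligonucleotide, and 200 pg of cDNA entered a Nextera XT reaction at 1/5 volume. The libraries were sequenced as paired reads of 151 cycles on an Illumina HiSeq, 26 samples per lane. Per the submitters' processing notes, the authors aligned reads with STAR to GRCm38 and made the deposited count table with featureCounts, with versions not given. The notes do not state the strand setting, the handling of reads with several positions or whether read pairs or single mates were counted. Antisense and overlapping genes, pseudogene families such as that of Gapdh and immunoglobulin variable segments are therefore uncertain.

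The deposited table holds raw whole-number counts for 54752 features in 33 libraries, of which 54723 have a gene symbol, 28239 have any count and 0 are spike-in features. Of counts from 1 to 10, 76.2% were even, as when both mates of a pair are counted. Totals ran from 5.52 to 40 Mcounts (megacounts) per library. Groups follow the labels, with 11 groups of 3 biological replicates. Replicate pairs had Pearson correlations of log2 CPM from 0.877 to 0.96.

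All 33 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (18198 genes kept) and robust quasi-likelihood tests, giving a biological coefficient of variation of 0.472 and 22 residual degrees of freedom. Tests covered 7 comparisons of control populations, sepsis against control in 4 populations, the mean of those 4 effects, and an interaction test of whether the 4 effects differ. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 for each test separately. Gene sets were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, and p-values were adjusted over the 300 tests of 25 lists in 12 contrasts. The directional p of fry asks whether the genes of a set move on balance one way and its mixed p whether they change in either direction; neither compares the set with other genes. The gene lists covered azurophil granules, specific granules, late neutrophil genes, monocyte genes, stem and progenitor genes, DNA replication, G2 and M phase, ribosome biogenesis, interferon, NF-kB and STAT3 responses, glycolysis, oxidative phosphorylation, cholesterol synthesis, ER chaperones, the NADPH oxidase, immediate early genes, and markers of dendritic, B, T and NK, erythroid, megakaryocyte, eosinophil, basophil and mast, and macrophage cells. The panels of lineage transcription factors, surface markers and cytokine receptors, and a fixed panel of 20 genes, were counted without a set test.

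Genes are named by a rule set before the data were examined. It takes, per comparison, the 5 called genes with the largest rise and the 5 with the largest fall among genes at 20 CPM or more in the higher group and without overlap between groups, leaving out predicted genes, pseudogenes and spike-ins. It adds, per list, the 2 called members with the largest rise and the 2 with the largest fall (and the 3 most abundant members of lists of other cell types), the fixed panel, the 10 highest and 10 lowest genes of the mean sepsis effect, and the 10 genes with the lowest interaction p at 20 CPM or more. From these the text gives mostly genes whose call held in the alternatives, a choice made after the alternatives were seen.

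The methods were tried on simulated data with 200 changed genes among 18198. The changed genes were taken from the more abundant ones, so the recovery shares apply to those. Counts were drawn with the spread that edgeR estimated from the real data, which may favour edgeR. edgeR recovered 48%, 52%, 49% and 53% of 2-fold and 85%, 84%, 87% and 87% of 4-fold changes in sepsis Ly6C- GMP, proNeu1, proNeu2 and preNeu, and 6.34%, 4.23%, 3.55% and 2.78% of its calls were false. For the mean effect it recovered 90% and 99% with 5.5% false calls, and for the interaction 28% and 69%. In the same trial for Ly6C- GMP, 25.7% of the calls of limma and 18% of those of DESeq2 1.42.0 were false. The counts of both tools are given as alternatives only. Alternatives set before the data were examined were DESeq2, limma with voomWithQualityWeights, a test against a fold change of 1.5, RLE factors, no or a stricter filter, only the libraries compared, leaving out each library and leaving out each population from the mean. Halved counts, leaving out the 5 shallow libraries and leaving out the sex chromosomes were chosen after seeing the data. Spike-in scaling was not run because the table used here holds 0 spike-in features.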

Results

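Bulk RNA sequencing libraries were made from 11 groups of cells sorted from mouse bone marrow, with 3 libraries in each group and 33 libraries in all. The 7 control groups were Ly6C-negative granulocyte-monocyte progenitors (Ly6C- GMP), the neutrophil-path stages proNeu1, proNeu2 and preNeu, the common monocyte progenitor (cMoP), the transitional pre-monocyte (TpMo) and the Ly6C-high (Ly6Chi) monocyte. The other 4 groups held Ly6C- GMP, proNeu1, proNeu2 and preNeu collected 3 days after mid-grade caecal ligation and puncture, a surgical model of abdominal sepsis. Total counts per library ranged from 5.52 to 40 Mcounts (megacounts). The 5 shallow libraries were proNeu1 replicate 1, preNeu replicate 3, Ly6Chi monocyte replicate 2, sepsis proNeu1 replicate 1 and sepsis preNeu replicate 3, with at most 6.78 Mcounts each, and every other library had at least 17.2 Mcounts. The 3 libraries of each group are described as biological replicates, so the p-values measure the spread between biological replicates. Values are mean CPM (counts per megacount) ± SD with n = 3 libraries per group. Changes are log2 fold changes ± SE with a p adjusted over 18198 tested genes. The genes with the 5 largest rises and 5 largest falls of a comparison were taken among those whose library values did not overlap between the groups, which chance alone gives for 10% of genes.

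The first principal component held 28.1% of the variance and placed the monocyte path apart from the neutrophil path. Ly6Chi monocytes lay at 205.4 to 209.3, TpMo at 130.2 to 134 and cMoP at 36.74 to 40.73 on this component. The second component held 16.3% and ran from Ly6C- GMP to preNeu. The third held 7.78%, with all 12 sepsis libraries at positive values of 18.45 to 65.57 and all control neutrophil-path libraries at negative values. It was not particular to sepsis, since control cMoP lay at 26.29 to 29.79 and control TpMo at 10.5 to 17.65. Ly6Chi monocytes lay at -14.86 to -10.11. Mitochondrial genes took 0.711% to 3.07% of the counts of a library.

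**Figure D1:**
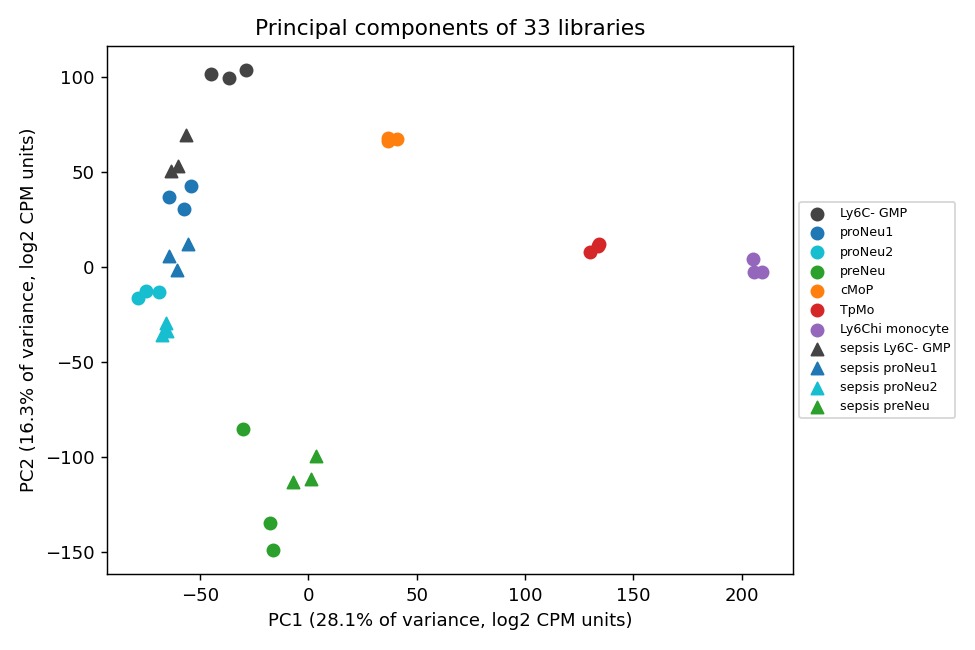
Each point is 1 of 33 libraries, placed by its scores on the first component (x axis, 28.1% of variance) and the second component (y axis, 16.3% of variance) of log2 CPM; circles are control and triangles are sepsis libraries. Ly6Chi monocyte libraries lie at 205.4 to 209.3 on the x axis and cMoP libraries at 36.74 to 40.73.

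Genes of a panel fixed before the data were examined differed between control populations, though not at every step. Mpo, which encodes myeloperoxidase, was at 34440 ± 4160 CPM in Ly6C- GMP, 55720 ± 2850 in proNeu1, 65300 ± 5290 in proNeu2 and 9449 ± 3900 in preNeu, against 20890 ± 1620 in cMoP and 41.03 ± 2.2 in Ly6Chi monocytes. Irf8, a transcription factor of monocyte and dendritic cell development, was at 194.9 ± 37.8 CPM in Ly6C- GMP, 192.1 ± 29.9 in proNeu1, 5.63 ± 3.25 in proNeu2 and 1524 ± 89.9 in cMoP. Gfi1, a transcriptional repressor needed for neutrophil development, was at 23.0 ± 4.79, 38.65 ± 3.18 and 70.04 ± 16.7 CPM in Ly6C- GMP, proNeu1 and proNeu2, and at 5.60 ± 0.361 in cMoP. Gfi1 was called neither in proNeu1 against Ly6C- GMP (adjusted p = 0.127) nor in proNeu2 against proNeu1 (adjusted p = 0.0922). Mpo was not called in proNeu2 against proNeu1 (adjusted p = 0.475), nor was Irf8 in proNeu1 against Ly6C- GMP. Csf1r, the receptor for macrophage colony-stimulating factor, was at 663.6 ± 76.9 CPM in cMoP, 990.1 ± 15.8 in TpMo and 1890 ± 541 in Ly6Chi monocytes, and at 51.06 ± 6.2 in Ly6C- GMP. Transcripts of the sex chromosomes differed between the paths. Xist, expressed from the inactive X chromosome of females, was at 353.8 ± 44.4 to 492.8 ± 9.32 CPM in the control neutrophil-path groups and at no more than 0.554 CPM on average in cMoP, TpMo and Ly6Chi monocytes. Ddx3y, a Y-linked gene, was at 77.29 ± 14.3 to 82.49 ± 10.5 CPM in those 3 monocyte groups and at no more than 0.374 CPM on average elsewhere. All 9 monocyte-path libraries thus carried male and the other 24 libraries female transcripts, and comparisons between the paths also compare animals of different sex.

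**Figure D2:**
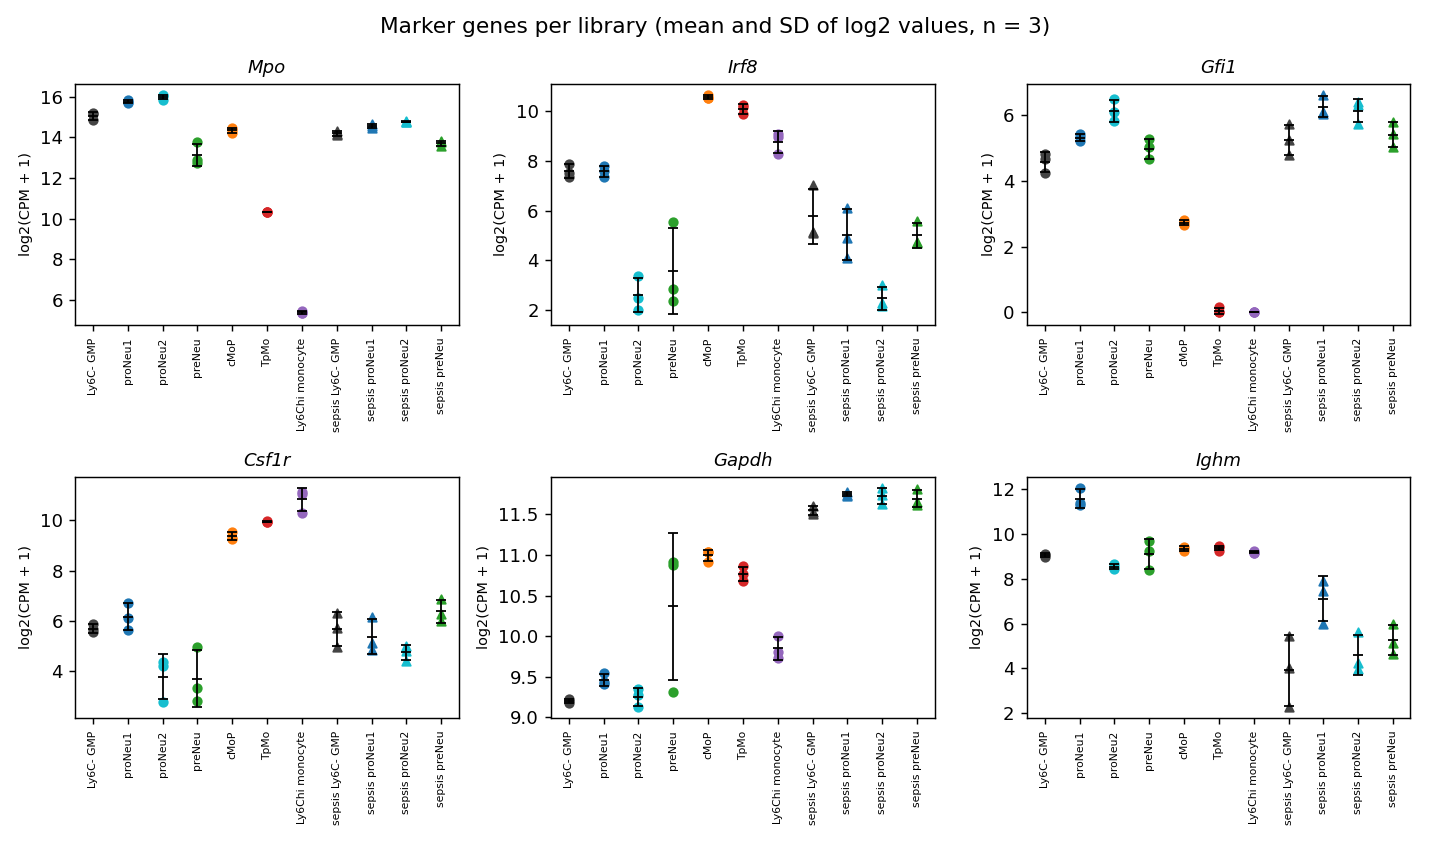
Points show log2(CPM + 1) of 6 genes (y axes) in each library by group (x axes), with the mean and SD of the 3 log2 values drawn in black; circles are control and triangles are sepsis libraries. Irf8 has a mean of 1524 CPM in cMoP and 5.63 in proNeu2, and Gapdh has means of 2997 to 3439 CPM in the sepsis groups.

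The step from Ly6C- GMP to proNeu1 addresses which genes mark the entry into the neutrophil path. Ltf (ENSMUSG00000032496.7, GRCm38 chromosome 9, 111019271 to 111042767), which encodes the iron-binding granule protein lactoferrin, rose from 21.93 ± 4.52 to 936.5 ± 372 CPM, a log2 change of 5.42 ± 0.50 (adjusted p = 1.39e-08). Cd177 (ENSMUSG00000052212.6, chromosome 7, 24743983 to 24760311), a neutrophil surface protein, rose from 9.15 ± 6.53 to 287.1 ± 124 CPM (4.97 ± 0.46, adjusted p = 1.39e-08). Prg2, which encodes eosinophil major basic protein, was lower at 24.21 ± 5.07 against 3846 ± 1230 CPM (-7.33 ± 0.54, adjusted p = 1.6e-10). H2-Ab1, an MHC class II gene, was also lower, at 14 ± 1.68 against 1195 ± 182 CPM (-6.43 ± 0.41, adjusted p = 2.27e-11).

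Among the gene lists fixed before the data were examined, the specific granule list moved furthest upward in proNeu1. Of its 17 measured genes, 16 rose, 0 fell and 1 was not called, with 16 higher adjusted over the list alone and a median log2 change of 3.57 (set test adjusted p = 1.43e-60). Examples were Ngp at 4.86 ± 0.56 and Camp, which encodes cathelicidin, at 4.80 ± 0.44. Levels in proNeu1 stayed far under those in preNeu, where Ltf was at 39320 ± 9150 and Camp at 5523 ± 1180 CPM. From proNeu1 to proNeu2 Ltf was not called (-1.15 ± 0.42, adjusted p = 0.141). Whether proNeu1 cells or later cells in the sort gate held these transcripts was not tested. The 11 azurophil granule genes gave 5 higher, 0 lower and 6 not called (8 higher adjusted over the list alone, set test adjusted p = 4.37e-09), among them the neutrophil elastase gene Elane at 1.29 ± 0.22. Of the 6 genes of the phagocyte NADPH oxidase, 5 rose (6 adjusted over the list alone, set test adjusted p = 1.55e-21), with Cybb at 2.89 ± 0.21. Late neutrophil genes gave 9 higher, 1 lower and 14 not called of 24 (12 higher and 3 lower adjusted over the list alone, set test adjusted p = 2.83e-08), with S100a8 at 4.83 ± 0.34. DNA replication genes gave 6 higher and 18 not called of 24, with 15 higher adjusted over the list alone (set test adjusted p = 2.45e-08, and adjusted p = 0.116 with an estimated correlation). The set test of the G2 and M phase list gave an adjusted p of 0.239.

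Eosinophil, basophil and mast cell, dendritic cell and megakaryocyte genes were lower in proNeu1 than in Ly6C- GMP, and the erythroid list was not called (1 lower and 11 not called of 12, with 1 lower adjusted over the list alone, set test adjusted p = 0.94). The eosinophil list had 7 of 9 genes lower (7 adjusted over the list alone, set test adjusted p = 2.48e-24), with Epx, eosinophil peroxidase, at -7.27 ± 0.48. The basophil and mast cell list had 7 of 8 lower (7 adjusted over the list alone, set test adjusted p = 1.49e-22), with the protease genes Prss34 at -6.88 ± 0.65 and Cpa3 at -6.42 ± 0.49. MHC class II and dendritic cell genes had 10 of 14 lower and 4 not called (11 adjusted over the list alone, set test adjusted p = 8.09e-20), and megakaryocyte genes 2 of 8 lower and 6 not called (5 adjusted over the list alone, set test adjusted p = 2.97e-06). Among 20 stem and early progenitor genes, 6 fell, 0 rose and 14 were not called (11 lower adjusted over the list alone, set test adjusted p = 7.75e-08), with Gata2, a transcription factor of stem and mast cells, at -5.49 ± 0.89. Gcsam had 0 counts in proNeu1 against 23.69 ± 5.33 CPM in Ly6C- GMP. Ighm, the constant region of the IgM heavy chain, moved the other way and was at 3152 ± 997 CPM in proNeu1 and 531.2 ± 30.5 in Ly6C- GMP (2.57 ± 0.54, adjusted p = 0.00237), while the other 8 measured B lineage markers, Igkc among them (2.31 ± 0.98, adjusted p = 0.189), were not called. The T and NK cell list had 4 measured members, and its set test gave an adjusted p of 0.439.

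The fit called 1100 genes between proNeu1 and Ly6C- GMP, 654 higher and 446 lower. Of these, 313 higher and 358 lower genes changed at least 2-fold. Without proNeu1 replicate 3 the count was 711, and against a fold change of 1.5 it was 397. Among the tests by camera, 300 in all over 25 lists and 12 contrasts, 173 passed with the preset correlation. Of these, 84 also passed with an estimated correlation. A list call held with the estimated correlation unless its adjusted p is given here. The median, the mean and the direction of the set test differed in sign in 36 of the 300 tests, and 0 of those 36 were called.

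**Figure D3:**
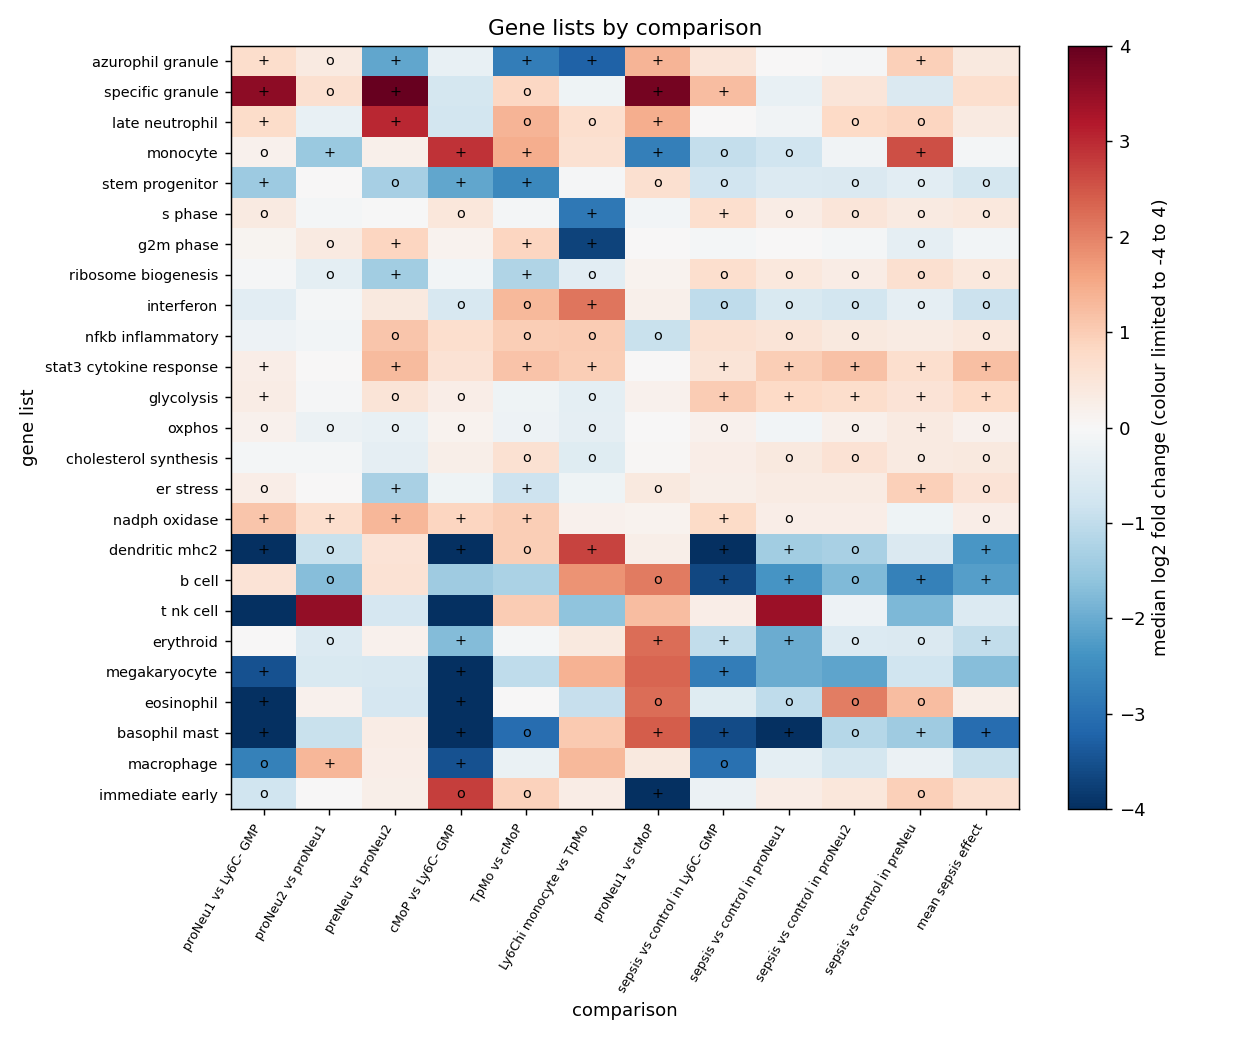
Colour gives the median log2 fold change of each gene list (y axis) in each comparison (x axis); a plus marks a call with both the preset and an estimated correlation and a circle marks a call with the preset correlation only. The specific granule list has a median of 3.57 in proNeu1 against Ly6C- GMP, and the glycolysis list has medians of 1.01, 0.793, 0.705 and 0.532 in the 4 sepsis comparisons.

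Between proNeu1 and proNeu2, the 2 successive early neutrophil stages, monocyte-associated genes fell. Irf8 (ENSMUSG00000041515.10, chromosome 8, 120736358 to 120756694) fell from 192.1 ± 29.9 to 5.63 ± 3.25 CPM (-5.09 ± 0.70, adjusted p = 9.21e-05). Ccr2, the chemokine receptor of inflammatory monocytes, fell from 54.41 ± 7.92 to 3.99 ± 3.02 CPM (-3.76 ± 0.46, adjusted p = 1.43e-05). Vcam1 (ENSMUSG00000027962.14, chromosome 3, 116109949 to 116129688), an adhesion molecule, rose from 63.2 ± 2.62 to 637.5 ± 66.7 CPM (3.33 ± 0.41, adjusted p = 1.43e-05). Of 18 monocyte genes, 10 fell, 1 rose and 7 were not called (11 lower and 1 higher adjusted over the list alone, set test adjusted p = 1.24e-12), including Csf1r at -2.37 ± 0.46. The progenitor marker Cd34 was at -3.52 ± 0.61, with 2 lower and 18 not called of 20 stem and progenitor genes (2 higher and 5 lower adjusted over the list alone, set test adjusted p = 0.0565). NADPH oxidase genes gave 3 higher and 3 not called of 6 (6 higher adjusted over the list alone, set test adjusted p = 2e-09). The specific granule list gave 4 higher and 13 not called of 17 (4 higher and 1 lower adjusted over the list alone, set test adjusted p = 0.000225, and adjusted p = 0.176 with an estimated correlation). The macrophage list gave 1 higher and 10 not called of 11 (4 higher adjusted over the list alone, set test adjusted p = 2.17e-05), and the called gene was Vcam1.

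Immunoglobulin transcripts were also lower in proNeu2 than in proNeu1. Ighm was at 371.6 ± 29.7 against 3152 ± 997 CPM (-3.09 ± 0.55). Igkc, the kappa light chain constant region, was at 27.08 ± 28.3 against 894.8 ± 464 CPM (-5.05 ± 1.11, adjusted p = 0.0112), and Jchain, which joins secreted immunoglobulin, at 13.2 ± 8.96 against 397.6 ± 156 CPM (-4.92 ± 1.09, adjusted p = 0.0112). Without proNeu2 replicate 1 both lost the call (adjusted p = 0.055 for each), and without proNeu2 replicate 3 the adjusted p was 0.069 for Igkc and 0.0636 for Jchain. The B lineage list had 2 of 9 genes lower (2 adjusted over the list alone, set test adjusted p = 0.0138, and adjusted p = 0.0652 with an estimated correlation). This step had the fewest called genes of the comparisons, 555 (285 higher and 270 lower; 104 and 205 at least 2-fold). That count was 1119 with DESeq2, 353 with only the libraries compared and 107 against a fold change of 1.5. Leaving out 1 library gave 300 (proNeu1 replicate 1), 297 (proNeu1 replicate 2), 147 higher and 187 lower (proNeu1 replicate 3), 226 (proNeu2 replicate 2) and 307 (proNeu2 replicate 3).

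From proNeu2 to preNeu, specific granule and late neutrophil genes rose and azurophil granule genes fell. Lcn2 (ENSMUSG00000026822.14, chromosome 2, 32384633 to 32388252), which encodes the iron-siderophore binding protein lipocalin, rose from 24.55 ± 11 to 2495 ± 1170 CPM (6.67 ± 0.38, adjusted p = 2.49e-13), and Ltf from 422.9 ± 201 to 39320 ± 9150 CPM (6.54 ± 0.53, adjusted p = 2.58e-10). Mpo (ENSMUSG00000009350.13, chromosome 11, 87793581 to 87804413) fell from 65300 ± 5290 to 9449 ± 3900 CPM (-2.79 ± 0.16, adjusted p = 4.65e-13). All 17 specific granule genes were higher (17 adjusted over the list alone, median log2 change 4.24, set test adjusted p = 2.74e-23). Late neutrophil genes gave 15 higher and 9 not called of 24 (15 adjusted over the list alone, set test adjusted p = 5.01e-09), with the matrix metalloprotease gene Mmp25 at 7.05 ± 0.91 and the formyl peptide receptor gene Fpr2 at 7.19 ± 1.16. Of 11 azurophil granule genes, 10 fell and 1 rose, with the same counts adjusted over the list alone (set test adjusted p = 2.92e-14). Control preNeu replicate 3 lay nearer to proNeu2 than the other preNeu libraries did, with a mean log2 CPM of the azurophil list of 9.44 against 8.26 and 8.59, and of the ribosome biogenesis list of 5.94 against 4.79 and 5.05. Ly6g, the surface marker of mature mouse neutrophils, was at 79.06 ± 26.6 against 0.704 ± 1.22 CPM (6.79 ± 1.18, adjusted p = 6.64e-05).

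Cell division and biosynthesis genes also changed between proNeu2 and preNeu. The G2 and M phase list gave 23 higher and 1 not called of 24 (23 adjusted over the list alone, median log2 change 0.864, set test adjusted p = 7.11e-16). Kif23 was at 1.97 ± 0.20 and Ccna2 at 1.73 ± 0.14. The replication list gave 6 higher, 5 lower and 13 not called of 24 with the same counts adjusted over the list alone (set test adjusted p = 0.973). Ribosome biogenesis genes gave 22 lower and 2 not called of 24 (24 lower adjusted over the list alone, median -1.4, set test adjusted p = 2.37e-22), with Nop16 at -3.09 ± 0.22. ER chaperone and unfolded protein response genes gave 16 lower and 5 not called of 21 (16 lower and 1 higher adjusted over the list alone, set test adjusted p = 4.55e-14), with Manf at -2.29 ± 0.21. All 6 NADPH oxidase genes rose (6 adjusted over the list alone, set test adjusted p = 2.62e-12). The list of G-CSF, IL-6 and STAT3 response genes gave 9 higher, 1 lower and 9 not called of 19 (9 higher and 2 lower adjusted over the list alone, set test adjusted p = 0.000287). NF-kB response genes gave 10 higher, 2 lower and 9 not called of 21 with the same counts adjusted over the list alone (set test adjusted p = 0.00103, and adjusted p = 0.106 with an estimated correlation). Of 24 genes in the panel of cytokine and chemokine receptors, 13 rose, 2 fell and 9 were not called, with the same counts adjusted over the list alone, and Csf2rb2 was at 3.76 ± 0.42. This comparison had 5060 called genes, 2377 higher and 2683 lower, with 1469 and 1619 at least 2-fold, and 2473 against a fold change of 1.5.

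The monocyte path began with the comparison of cMoP and Ly6C- GMP. Ly6c2, which encodes the Ly6C surface marker, rose from 123.3 ± 29.6 to 2812 ± 312 CPM (4.51 ± 0.22, adjusted p = 2.16e-14). Csf1r (ENSMUSG00000024621.15, chromosome 18, 61105572 to 61132149) rose from 51.06 ± 6.2 to 663.6 ± 76.9 CPM (3.70 ± 0.47, adjusted p = 1.41e-06) and Irf8 from 194.9 ± 37.8 to 1524 ± 89.9 CPM (2.97 ± 0.61, adjusted p = 0.000825). Cebpe, a transcription factor of late granulocyte differentiation, fell from 195.1 ± 32.7 to 9.39 ± 4.46 CPM (-4.36 ± 0.49, adjusted p = 1.57e-07). Of 18 monocyte genes, 15 rose and 3 were not called (16 adjusted over the list alone, set test adjusted p = 6.72e-20), including Klf4 at 4.59 ± 0.71. Stem and progenitor genes gave 16 lower and 4 not called of 20 (16 adjusted over the list alone, set test adjusted p = 4.99e-13). In the panel of 26 measured lineage transcription factors, 4 rose, 11 fell and 11 were not called (6 higher and 13 lower adjusted over the list alone).

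The transcripts of other lineages found in Ly6C- GMP were lower in cMoP as well. All 9 eosinophil genes fell (9 adjusted over the list alone, set test adjusted p = 4.75e-20), with Prg2 at -10.17 ± 0.62, and all 8 basophil and mast cell genes fell (8 adjusted over the list alone, set test adjusted p = 2.59e-21), with Prss34 at -10.75 ± 0.77. Erythroid genes gave 6 lower and 6 not called of 12 (6 adjusted over the list alone, set test adjusted p = 1.37e-06), and megakaryocyte genes gave 6 lower and 2 not called of 8 (8 adjusted over the list alone, set test adjusted p = 8.17e-06). Slc22a3 had 0 counts in cMoP against 77.45 ± 15 CPM in Ly6C- GMP. Immediate early and heat shock genes were higher in cMoP, with 8 of 16 called and 8 not (10 higher adjusted over the list alone, set test adjusted p = 5.38e-05, and adjusted p = 0.146 with an estimated correlation), and Hspa1a was at 4.52 ± 0.76. Y-linked genes such as Eif2s3y, at 9.14 ± 0.58, were among the largest increases in this comparison. The fit called 3126 genes, 1677 higher and 1449 lower (877 and 839 at least 2-fold), and 3032 of them lay off the X and Y chromosomes (1620 higher and 1412 lower). The count was 4958 with limma and 1201 against a fold change of 1.5.

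Between cMoP and TpMo, progenitor and azurophil granule genes fell while genes of monocyte function rose. Kit (ENSMUSG00000005672.12, chromosome 5, 75574916 to 75656722), the stem cell factor receptor, fell from 187.2 ± 28.9 to 0.845 ± 0.517 CPM (-7.82 ± 0.28, adjusted p = 1.25e-17), and Mpo from 20890 ± 1620 to 1283 ± 10.7 CPM (-4.03 ± 0.17, adjusted p = 5.05e-16). Fn1 (ENSMUSG00000026193.15, chromosome 1, 71585520 to 71653200), which encodes fibronectin, rose from 84.66 ± 5 to 4272 ± 136 CPM (5.66 ± 0.75, adjusted p = 2.49e-06), and the Src-family kinase gene Fgr from 2.70 ± 0.746 to 173.8 ± 7.55 CPM (5.99 ± 0.57, adjusted p = 8.41e-09). Of 11 azurophil granule genes, 10 fell and 1 rose, with the same counts adjusted over the list alone (median log2 change -2.77, set test adjusted p = 1.08e-36). Monocyte genes gave 10 higher, 1 lower and 7 not called of 18 with the same counts adjusted over the list alone (set test adjusted p = 3.65e-07). The G2 and M phase list gave 21 higher and 3 not called of 24 (23 adjusted over the list alone, set test adjusted p = 4.18e-20), with Mki67 at 1.38 ± 0.17. All 24 ribosome biogenesis genes fell (24 adjusted over the list alone, median -1.21, set test adjusted p = 7.38e-19). ER chaperone genes gave 15 lower and 6 not called of 21 (15 adjusted over the list alone, set test adjusted p = 1.36e-10), with Calr at -2.41 ± 0.26. Cholesterol synthesis genes gave 8 higher, 1 lower and 10 not called of 19 with the same counts adjusted over the list alone (set test adjusted p = 0.00312, and adjusted p = 0.116 with an estimated correlation). The fit called 3290 genes, 1733 higher and 1557 lower (868 and 884 at least 2-fold), against 5405 with limma and 1254 against a fold change of 1.5.

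Genes of cell division were lower in Ly6Chi monocytes than in TpMo. Kif11, a mitotic motor, fell from 622.4 ± 65.3 to 18.3 ± 3.51 CPM (-5.07 ± 0.16, adjusted p = 2.74e-19), and Rrm2, a subunit of ribonucleotide reductase, from 783 ± 63.1 to 34.89 ± 8.42 CPM (-4.47 ± 0.18, adjusted p = 3.12e-17). All 24 replication genes (24 adjusted over the list alone, median log2 change -2.86, set test adjusted p = 9.52e-100) and all 24 G2 and M phase genes (24 adjusted over the list alone, median -3.69, set test adjusted p = 4.08e-137) fell. Interferon-stimulated genes gave 27 higher and 4 not called of 31 (28 adjusted over the list alone, set test adjusted p = 7.97e-13), with Ifit1 at 5.27 ± 0.99. MHC class II and dendritic cell genes gave 6 higher and 8 not called of 14 (6 adjusted over the list alone, set test adjusted p = 0.000262), with H2-Aa at 80.15 ± 52.4 against 1.44 ± 1.01 CPM (5.83 ± 0.72). Mpo continued lower, at 41.03 ± 2.2 CPM (-4.96 ± 0.18), and 9 of 11 azurophil granule genes fell (9 lower and 1 higher adjusted over the list alone, set test adjusted p = 7.96e-20). In the panel of 18 surface marker genes, 6 rose, 6 fell and 6 were not called (7 higher and 7 lower adjusted over the list alone), with the chemokine receptor gene Cxcr4 at -2.24 ± 0.30. The fit called 3802 genes, 1382 higher and 2420 lower (791 and 1447 at least 2-fold), and 1719 against a fold change of 1.5.

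The comparison of proNeu1 with cMoP sets the earliest stages of the 2 paths side by side. Neutrophil-path genes were higher in proNeu1, with Camp at 199.2 ± 79.9 against 2.55 ± 0.698 CPM (6.29 ± 0.49, adjusted p = 3.02e-10), Cebpe at 238.2 ± 40.8 against 9.39 ± 4.46 CPM (4.65 ± 0.50, adjusted p = 9.47e-08) and Gfi1 at 2.78 ± 0.30. Monocyte genes were lower, with Csf1r at -3.16 ± 0.46, Irf8 at -2.99 ± 0.61 and the secreted matrix protein gene Tgfbi at -3.68 ± 0.24. The lists gave 14 of 17 specific granule genes higher and 3 not called (14 adjusted over the list alone, set test adjusted p = 1.06e-27), and 7 higher, 1 lower and 3 not called of 11 azurophil granule genes (9 higher and 1 lower adjusted over the list alone, set test adjusted p = 1.58e-10). They gave 15 lower, 1 higher and 2 not called of 18 monocyte genes (16 lower and 1 higher adjusted over the list alone, set test adjusted p = 9.94e-16). Markers of other lineages were higher in proNeu1. Erythroid genes gave 6 higher and 6 not called of 12 (7 adjusted over the list alone, set test adjusted p = 5.68e-07), with Car2, a carbonic anhydrase, at 4.63 ± 0.41, and basophil and mast cell genes 6 higher and 2 not called of 8 (6 adjusted over the list alone, set test adjusted p = 1.36e-05). Immediate early and heat shock genes gave 12 lower and 4 not called of 16 (12 adjusted over the list alone, set test adjusted p = 1.12e-08). Fosb was at -6.78 ± 1.32. Igkv15-103 was at 101 ± 63.7 CPM in proNeu1 with 0 counts in cMoP. Variable segments of immunoglobulin genes share reads with their paralogs, so the identity of the segment is uncertain. The fit called 2963 genes, 1502 higher and 1461 lower (722 and 854 at least 2-fold). Of these 2879 lay off the X and Y chromosomes, and 1062 passed against a fold change of 1.5.

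**Figure D4:**
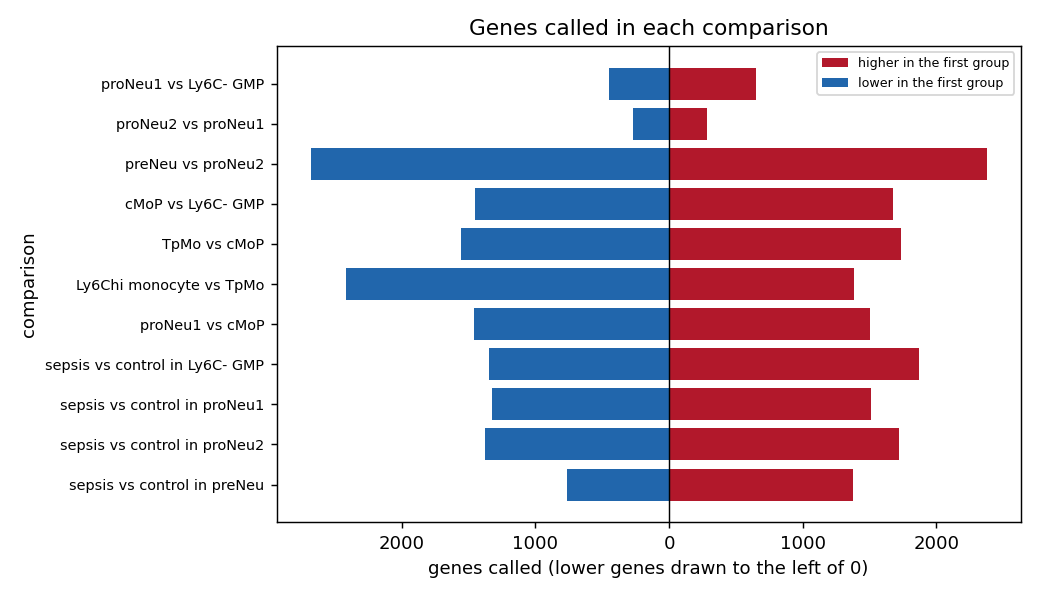
Bars give the number of genes called at an adjusted p under 0.05 in each of 11 comparisons (y axis), with genes higher in the first-named group to the right of 0 and genes lower to the left (x axis, genes). The preNeu and proNeu2 comparison has 2377 higher and 2683 lower genes, and proNeu2 against proNeu1 has 285 and 270.

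The sepsis comparisons ask how each neutrophil-path population differed 3 days after caecal ligation and puncture. In Ly6C- GMP, Lipg (ENSMUSG00000053846.4, chromosome 18, 74939322 to 74961263), which encodes endothelial lipase, rose from 0.148 ± 0.118 to 51.3 ± 18.4 CPM (8.34 ± 0.68, adjusted p = 1.37e-09). Dgat2, an enzyme of triglyceride synthesis, rose from 14.37 ± 3.85 to 328.1 ± 68.5 CPM (4.51 ± 0.24, adjusted p = 7.81e-13), and the decoy receptor gene Il1r2 was at 4.75 ± 0.59. Gapdh (ENSMUSG00000057666.18, chromosome 6, 125161715 to 125166467), a glycolytic enzyme with many pseudogenes, rose from 587 ± 11.3 to 2997 ± 107 CPM (2.35 ± 0.21, adjusted p = 6.92e-09). Cd74 (ENSMUSG00000024610.14, chromosome 18, 60803848 to 60812646), the invariant chain of MHC class II, fell from 1104 ± 198 to 3.35 ± 0.791 CPM (-8.37 ± 0.67, adjusted p = 1.16e-09).

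The lists in sepsis Ly6C- GMP showed 14 of 18 glycolysis genes higher, 1 lower and 3 not called with the same counts adjusted over the list alone (median 1.01, set test adjusted p = 4.18e-20), including the glucose transporter gene Slc2a1 at 2.04 ± 0.31. Replication genes gave 16 higher and 8 not called of 24 (18 adjusted over the list alone, set test adjusted p = 5.73e-12), with the cyclin gene Ccne1 at 2.61 ± 0.38. Specific granule genes gave 8 higher and 9 not called of 17 (10 higher and 1 lower adjusted over the list alone, set test adjusted p = 5.82e-09), with Lcn2 at 4.31 ± 0.35 and Lrg1 at 3.95 ± 0.47. Ribosome biogenesis genes gave 13 higher and 11 not called of 24 (14 adjusted over the list alone, set test adjusted p = 1.21e-06, and adjusted p = 0.22 with an estimated correlation). Response genes of G-CSF, IL-6 and STAT3 gave 9 higher and 10 not called of 19 (9 adjusted over the list alone, set test adjusted p = 2.85e-06). MHC class II and dendritic cell genes gave 12 lower and 2 not called of 14 (13 adjusted over the list alone, set test adjusted p = 2.54e-20), with H2-Aa at -7.81 ± 0.76 and the class II transactivator gene Ciita at -8.02 ± 1.59. All 8 basophil and mast cell genes fell (8 adjusted over the list alone, set test adjusted p = 9.38e-10), with Prss34 at 285.4 ± 242 against 6159 ± 1160 CPM. B lineage genes gave 3 lower and 6 not called of 9 (4 adjusted over the list alone, set test adjusted p = 0.000812), with Ighm at 20.5 ± 19.8 against 531.2 ± 30.5 CPM. Interferon-stimulated genes gave 13 lower and 18 not called of 31 (18 adjusted over the list alone, set test adjusted p = 4.26e-07, and adjusted p = 0.057 with an estimated correlation). Macrophage markers gave 4 lower and 7 not called of 11 (8 adjusted over the list alone, set test adjusted p = 0.001, and adjusted p = 0.0845 with an estimated correlation). The fit called 3223 genes, 1872 higher and 1351 lower (788 and 743 at least 2-fold), and 868 against a fold change of 1.5.

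In proNeu1, Lipg rose from 1.01 ± 0.825 to 130.1 ± 47.1 CPM (6.85 ± 0.57, adjusted p = 6.58e-09), and Clu, which encodes the secreted chaperone clusterin, from 2.92 ± 1.18 to 140.5 ± 24.3 CPM (5.64 ± 0.69, adjusted p = 1.73e-06). Cebpb, a transcription factor of emergency granulopoiesis, was at 27.34 ± 5.7 against 0.0639 ± 0.0601 CPM (8.20 ± 2.14, adjusted p = 0.00834). Ltf fell from 936.5 ± 372 to 34.28 ± 5.55 CPM (-4.76 ± 0.49, adjusted p = 1.39e-07), Camp was at -3.35 ± 0.41 and Elane fell from 17060 ± 394 to 5809 ± 685 CPM (-1.55 ± 0.23, adjusted p = 1.87e-05), while Lcn2 rose by 2.36 ± 0.31. The specific granule list gave 3 higher, 5 lower and 9 not called of 17 (5 higher and 6 lower adjusted over the list alone, set test adjusted p = 0.302). Glycolysis genes gave 12 higher, 1 lower and 5 not called of 18 (12 higher and 2 lower adjusted over the list alone, median 0.793, set test adjusted p = 1.04e-15). G-CSF, IL-6 and STAT3 response genes gave 8 higher, 1 lower and 10 not called of 19 (9 higher and 1 lower adjusted over the list alone, set test adjusted p = 0.000315). Erythroid genes gave 5 lower and 7 not called of 12 (6 adjusted over the list alone, set test adjusted p = 6.73e-06), with the transcription factor gene Klf1 at -4.89 ± 0.66. The B lineage list gave 2 lower and 7 not called of 9 (2 adjusted over the list alone, set test adjusted p = 0.0025), Ighm and Igkc, with Ighm at 157.4 ± 88.9 against 3152 ± 997 CPM. The fit called 2839 genes, 1511 higher and 1328 lower (652 and 669 at least 2-fold). The count was 1745 without the 5 shallow libraries, 1880 without sepsis proNeu1 replicate 3 and 661 against a fold change of 1.5.

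In proNeu2 the same lipase transcript led the increases, with Lipg at 407.9 ± 97.6 against 4.604 ± 2.23 CPM (6.47 ± 0.53, adjusted p = 1.75e-09). The interferon-induced membrane protein genes Ifitm1 and Ifitm3 rose by 5.97 ± 0.41 and 4.76 ± 0.31, and Nrp2, a neuropilin receptor gene, by 5.01 ± 0.58. Vcam1 fell from 637.5 ± 66.7 to 141.4 ± 19.1 CPM (-2.17 ± 0.39, adjusted p = 0.000177), Cebpe from 492.2 ± 39.2 to 87.27 ± 50.5 CPM (-2.50 ± 0.44, adjusted p = 0.000182) and Kit from 392.3 ± 42.3 to 134.2 ± 4.77 CPM (-1.55 ± 0.19, adjusted p = 1.53e-06). Ighm (ENSMUSG00000076617.9, chromosome 12, 113418558 to 113422730) fell from 371.6 ± 29.7 to 27.06 ± 18.8 CPM (-3.78 ± 0.57, adjusted p = 2.31e-05). Glycolysis genes gave 11 higher, 1 lower and 6 not called of 18 (13 higher and 1 lower adjusted over the list alone, median 0.705, set test adjusted p = 7.73e-17). G-CSF, IL-6 and STAT3 response genes gave 7 higher and 12 not called of 19 (8 adjusted over the list alone, set test adjusted p = 0.000299). Eosinophil genes gave 5 higher and 4 not called of 9 (5 adjusted over the list alone, set test adjusted p = 0.000822, and adjusted p = 0.0677 with an estimated correlation), with Epx at 42.34 ± 20.5 against 6.18 ± 1.73 CPM (2.78 ± 0.41). Basophil and mast cell genes gave 4 lower and 4 not called of 8 (4 adjusted over the list alone, set test adjusted p = 0.0154, and adjusted p = 0.137 with an estimated correlation). Among NF-kB response genes 8 rose and 13 were not called of 21 (8 adjusted over the list alone, set test adjusted p = 0.00518, and adjusted p = 0.16 with an estimated correlation), with Relb at 5.40 ± 1.02. The fit called 3097 genes, 1719 higher and 1378 lower (770 and 699 at least 2-fold), 2060 without proNeu2 replicate 2 and 802 against a fold change of 1.5.

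In preNeu libraries, genes otherwise high in the monocyte path rose in sepsis. Whether preNeu cells or other cells in the sort gate held these transcripts was not tested. Fn1 rose from 4.43 ± 1.98 to 436.8 ± 281 CPM (6.75 ± 0.84, adjusted p = 2.24e-06), Ccr2 from 7.30 ± 5.56 to 135.3 ± 35.6 CPM (4.42 ± 0.48, adjusted p = 2.14e-07) and Csf1r from 15.19 ± 13.4 to 85.32 ± 27.9 CPM (2.64 ± 0.48, adjusted p = 0.000389). The monocyte list gave 13 higher, 1 lower and 4 not called of 18 (15 higher and 1 lower adjusted over the list alone, median 2.58, set test adjusted p = 1.47e-17). Of 11 azurophil granule genes, 8 rose and 3 were not called (8 adjusted over the list alone, set test adjusted p = 8.07e-13), with Ctsc, the cathepsin that activates granule proteases, at 315.7 ± 77.5 against 27.37 ± 13.5 CPM (3.57 ± 0.25, adjusted p = 1.41e-10). Control preNeu replicate 3 lay near the sepsis libraries in Mpo, which took 1.29% of its counts against 0.555% and 0.614% in the other controls and 1.14% to 1.28% in sepsis. Ltf fell from 39320 ± 9150 to 11480 ± 3380 CPM (-1.78 ± 0.43, adjusted p = 0.00539), Camp was at -1.86 ± 0.38 and Kit fell from 220.8 ± 17 to 27.59 ± 1.35 CPM (-3.00 ± 0.21, adjusted p = 6.35e-11). ER chaperone genes gave 13 higher and 8 not called of 21 (16 adjusted over the list alone, set test adjusted p = 1.4e-15), with Sdf2l1 at 1.77 ± 0.24. Glycolysis genes gave 11 higher, 1 lower and 6 not called of 18 (12 higher and 2 lower adjusted over the list alone, median 0.532, set test adjusted p = 2.76e-07). Oxidative phosphorylation genes gave 9 higher and 15 not called of 24 (14 adjusted over the list alone, set test adjusted p = 1.01e-08). G2 and M phase genes gave 9 lower and 15 not called of 24 (11 adjusted over the list alone, set test adjusted p = 3.66e-07, and adjusted p = 0.197 with an estimated correlation). Svep1 was at 31.38 ± 13.1 CPM with 0 counts in control preNeu. The fit called 2145 genes, 1378 higher and 767 lower (711 and 319 at least 2-fold), 1226 without preNeu replicate 1, 1219 with only the libraries compared and 517 against a fold change of 1.5.

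The mean of the 4 sepsis effects does not show by itself that an effect was shared, and its p treats the 4 populations as independent. In this mean Lipg rose by 6.62 ± 0.28 (adjusted p = 4.45e-16), Clu by 5.41 ± 0.35, Ifitm1 by 4.64 ± 0.19, Il1r2 by 3.59 ± 0.26, the pathogen receptor gene Tlr2 by 2.44 ± 0.12 and Gapdh by 2.07 ± 0.11. Socs3, a feedback inhibitor induced by cytokine signalling, was at 3.93 ± 0.55. Ighm (-4.17 ± 0.29, adjusted p = 5.78e-12), Prss34 (-4.14 ± 0.31), Cd74 (-3.88 ± 0.29), Plbd1 (-3.47 ± 0.20) and Klf1 (-3.33 ± 0.31) fell, though Cd74 alone was not called in preNeu (-1.34, adjusted p = 0.147). Glycolysis genes gave 15 higher, 2 lower and 1 not called of 18 with the same counts adjusted over the list alone (median 0.798, set test adjusted p = 2.1e-20). The lower genes were the hexokinase genes Hk2 at -0.36 ± 0.08 and Hk3 at -0.41 ± 0.06, which were not called against a fold change of 1.5. Interferon-stimulated genes gave 19 lower and 12 not called of 31 (19 adjusted over the list alone, set test adjusted p = 1.26e-05, and adjusted p = 0.112 with an estimated correlation). Granule genes went both ways, with Lcn2 at 2.65 ± 0.16 and Ltf at -2.14 ± 0.22, and the specific granule list gave 8 higher, 6 lower and 3 not called of 17 with the same counts adjusted over the list alone (set test adjusted p = 0.146). In the fixed panel of 20 genes, 5 rose, 13 fell and 2 were not called, with the same counts adjusted over the list alone. The mean effect was called in 6749 genes, 3568 higher and 3181 lower (1099 and 1033 at least 2-fold), and in 1742 genes against a fold change of 1.5.

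Calls overlapped between populations. Of all tested genes, 367 were higher in all 4 populations, against 1.11 if the 4 lists were independent, and 201 were lower in all 4, against 0.315. The independent counts take every gene as equally likely to be called. Abundant genes with little spread are called more easily in all 4 tests, so part of the excess needs no shared response. Together the 568 genes called the same way in all 4 became 63 against a fold change of 1.5. Called directions were opposite in at least 2 populations for 175 genes. Across genes, which are not independent replicates, the Pearson correlation of the sepsis effects ranged over 6 pairs from 0.177 for Ly6C- GMP with preNeu to 0.341 for Ly6C- GMP with proNeu1, and the Spearman correlation from 0.26 to 0.458 for the same pairs.

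The test of the difference itself called 1154 genes whose sepsis effect differed between the populations. H2-Ab1 fell by 6.80 in Ly6C- GMP, with changes of -0.76, -0.92 and -0.46 in proNeu1, proNeu2 and preNeu (adjusted p of the difference = 6.31e-09). Its control mean was 1195 CPM in Ly6C- GMP but 14, 12.76 and 9.89 CPM in the others, which left little room to fall. Ifitm1 changed by 1.42, 4.20, 5.97 and 6.95 in the same order (adjusted p of the difference = 1.4e-07). The monocyte-associated gene Emilin2 changed by 0.37, 3.25, 3.72 and 5.52 (adjusted p of the difference = 5.96e-08). Control means of Ifitm1 were 36.11, 2.06, 0.36 and 0.496 CPM, and sepsis means 96.67, 34.39, 23.14 and 59.27 CPM. For Emilin2 control means were 182.2, 20.7, 9.17 and 8.33 CPM, and sepsis means 236, 196.8, 121.1 and 354.2 CPM. Both genes thus changed least where their control level was highest. The cytoskeletal scaffold gene Ahnak had changes of -4.18, -3.27, -1.07 and 5.00 (adjusted p of the difference = 4.68e-09). The count was 2081 with the likelihood ratio test of DESeq2, 2227 with limma and 734 without preNeu replicate 2.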

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

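The tests for B cells, dendritic cells, the 3 tests on glycolysis and the test on cohort handling were chosen after the results were seen, and the test for plasma cells and the other splits of the samples before.

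A difference between groups drew attention to the sepsis effect, which differed between populations by the interaction test in 1154 genes. For the 10 such genes chosen by the rule, the highest effect minus the lowest over the 4 populations was 4.177 for Naaa, 9.18 for Ahnak, 2.449 for Tpd52, 6.34 for H2-Ab1, 5.429 for Pld4, 5.149 for Emilin2, 8.477 for Capn2, 5.534 for Ifitm1, 3.103 for Clec5a and 2.417 for Mcemp1 (log2). Of 100 splits of the libraries within populations, 7 gave as many genes, the real one included. The highest other split gave 3059 genes, which points to a structure of the samples: in all 6 other splits at least 1 population was left unmixed, so they hold the sepsis effect in part of the populations and this count says nothing on chance. The 56 splits with none unmixed gave at most 1 gene. They mix sepsis with control libraries everywhere. Mixing dilutes the sepsis effect and adds to the spread within groups, so these splits do not hold an equal effect at full size. They therefore say nothing on this question either. In the simulation with equal effects 0 genes were called, with all libraries drawn independently. The count was 734 without preNeu replicate 2.

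Ighm and Cd74 were lower in sepsis in Ly6C- GMP and proNeu1, while the class II gene H2-Ab1 was called in Ly6C- GMP and not in proNeu1 (-0.76, adjusted p = 0.157). Ighm was also lower in sepsis proNeu2 (27.06 against 371.6 CPM) and preNeu (40.02 against 589.9 CPM). Control Igkc was at only 27.08 and 49.92 CPM in proNeu2 and preNeu, and the source of Ighm was not tested there. In control proNeu1, the ratio of Jchain to Igkc was 0.462, and for 3 of 6 other plasma cell genes all sepsis proNeu1 libraries lay under all controls. Cd79a, Cd79b and Ms4a1 summed to 0.0159 of Ighm there on average and to 0.0203 in replicate 3. Most of this was Cd79b, which was also at 44.73 CPM in cMoP. Without Cd79b the ratio was 0.000756 in proNeu1 and 0.00559 in Ly6C- GMP, under the bound of 0.02 in each library. In proNeu1, with Ighm at 3152 CPM, this argues against B cells as the source of Ighm. In Ly6C- GMP the ratio cannot decide. Ighm was at 585.9 to 666.5 CPM in cMoP, TpMo and Ly6Chi monocytes, where Igkc was at no more than 1.92 CPM. Ighm thus reached such a level almost without light chain transcripts, which makes a small ratio likely with or without B cells. The ratio in Ly6C- GMP also depends more on the genes summed, and these genes were chosen after their values were seen. With Cd79b, at 47.91 CPM against 531.2 for Ighm, the ratio in Ly6C- GMP would lie over the bound of 0.02. Summed dendritic cell markers were 0.0547 of Cd74 in control Ly6C- GMP. In sepsis Ly6C- GMP, Xcr1 was at 0.0772 against 23.1 CPM in controls and Clec9a at 0 against 18.6. Itgax was at 0.154 against 7.48 CPM and Zbtb46 at 0.134 against 11.4, while Siglech was low in both (0.0712 and 0.142). These markers thus fell along with Cd74. The Jchain ratio passed the level set beforehand for plasma cells, but the other plasma cell genes followed only in part. The dendritic cell ratio lay between the levels set for and against such cells. Plasma or dendritic cells in the control gates and a change of expression in the sorted cells therefore cannot be told apart. The same holds for B cells in the control Ly6C- GMP gate.

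Glycolysis genes were higher in sepsis in all 4 populations. The 50 most abundant genes held 17.8% of the counts in control libraries of the 4 populations and 15.1% in sepsis libraries. Shares this close argue against a few abundant genes as the whole cause. Without those genes the median of the 13 glycolysis genes left was 0.814, with a lower quartile of 0.294. The removal could hardly have moved that median, so it adds little. Without Gapdh the median was 0.768, with a lower quartile of 0.288, so the rise did not rest on Gapdh alone. Removing 1 gene could hardly lower a median, so reads shared with pseudogenes remain untested. The range within a group was 0.0366 to 0.294 of the sepsis effect in 7 of 8 groups and 0.9 in control preNeu. Different animals or sort days remain open, since control and sepsis libraries may have been prepared apart.

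Immediate early and heat shock genes were higher in cMoP than in Ly6C- GMP and proNeu1. The lowest male library exceeded the highest female library by 0.713 in mean log2 CPM of the list, over 9 male and 24 female libraries. The handling of another cohort and a difference between the paths cannot be told apart, because all monocyte-path libraries are male.

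With 3 libraries against 3, the 10 splits are too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real counts and the highest of the other splits were 1100 and 8 for proNeu1 against Ly6C- GMP, 555 and 4 for proNeu2 against proNeu1, 5060 and 112 for preNeu against proNeu2, 3126 and 0 for cMoP against Ly6C- GMP, 3290 and 0 for TpMo against cMoP, 3802 and 17 for Ly6Chi monocytes against TpMo and 2963 and 1 for proNeu1 against cMoP. For sepsis they were 3223 and 1 in Ly6C- GMP, 2839 and 2 in proNeu1, 3097 and 2 in proNeu2, and 2145 and 86 in preNeu. For the mean effect, 1 of 100 splits gave as many genes (6749, highest other 2394). Chance can be excluded there if the populations are independent. For genes called the same way in all 4 populations it was also 1 of 100 (568, highest other 0). A split that mixes sepsis and control libraries in a population leaves few calls there. The 0 was thus close to fixed by the splits, and no conclusion on chance is drawn for this count. Replicate 1 had the highest mitochondrial share in all 8 neutrophil-path groups, as when equal numbers share an animal or a day; keeping such sets whole leaves 10 splits, too few for a share under 0.05.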

How the results depend on the processing

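Halved counts, leaving out the 5 shallow libraries and leaving out the sex chromosomes were alternatives chosen after seeing the data. RLE factors, both filters, halved counts and leaving out each of the 4 populations from the mean kept all counts of called genes they were run for within 1.5 times, and no result reversed. DESeq2 gave 1119 genes for proNeu2 against proNeu1 and 2081 for the difference between populations; limma gave 4958 for cMoP against Ly6C- GMP, 5405 for TpMo against cMoP and 2227 for the difference. The cause was not tested. In the simulation 18% and 25.7% of the calls of these tools were false. That trial of the 2 tools covered sepsis Ly6C- GMP only and used the spread estimated by edgeR. Its shares therefore do not carry over to these counts. Against a fold change of 1.5, a stricter question by construction, the counts were 397 (proNeu1 against Ly6C- GMP), 107 (proNeu2 against proNeu1), 2473 (preNeu against proNeu2), 1201 (cMoP), 1254 (TpMo), 1719 (Ly6Chi monocytes), 1062 (proNeu1 against cMoP), 868, 661, 802 and 517 (sepsis in Ly6C- GMP, proNeu1, proNeu2 and preNeu), 1742 (mean effect) and 63 (all 4). Without the shallow libraries sepsis proNeu1 gave 1745; with only the libraries compared, proNeu2 against proNeu1 gave 353 and sepsis preNeu 1219, and the cause was not tested. With an estimated correlation 84 of 173 list calls held, and with the stricter filter 145 held and 28 were lost. Leaving out each library gave 711 to 907 genes for proNeu1 against Ly6C- GMP, 226 to 446 for proNeu2 against proNeu1, 4031 to 5146 for preNeu, 2221 to 2580 for cMoP, 2471 to 2766 for TpMo, 2990 to 3399 for Ly6Chi monocytes and 2085 to 2409 for proNeu1 against cMoP. For sepsis it gave 2319 to 2588, 1880 to 2266, 2060 to 2694 and 1226 to 2646 in the 4 populations in the same order, 6329 to 6741 for the mean, 407 to 656 for all 4, 734 to 1403 for the difference and 169 to 179 list calls. Of the gene calls named by the rule that could be run, 982 held and 6 were lost with halved counts, 961 and 21 with DESeq2, 891 and 97 with limma, 890 and 98 with no filter, 893 and 95 without the shallow libraries, 845 and 85 with only the libraries compared, and 664 and 314 against a fold change of 1.5. Spike-in scaling and the spike-in share were not run. In sepsis Ly6C- GMP, 3187 of 3223 calls were also made with halved counts.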

Other observations

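The tests of the control maturation axis were chosen before the results were seen, but the rule that leaves a correlation open where other splits match it was made after. Ighm was at 653.1 ± 47.5 CPM in cMoP, 666.5 ± 49.6 in TpMo and 585.9 ± 16.6 in Ly6Chi monocytes, where Igkc was at 1.92, 0.245 and 0.884 CPM. Xist was at 228.5 ± 27.5, 160.8 ± 5.49, 181.6 ± 19.2 and 192.8 ± 30.3 CPM in sepsis Ly6C- GMP, proNeu1, proNeu2 and preNeu, against 492.8 ± 9.32, 353.8 ± 44.4, 389.9 ± 27.9 and 410.9 ± 41.5 CPM in the controls. Cd81, which encodes a tetraspanin, was at 407 ± 18.9 CPM in Ly6C- GMP and 97.12 in cMoP.

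A hypothesis was that sepsis moves each population along the control maturation axis, tested by the Pearson correlation across genes, which are not independent replicates, of the sepsis effect with the axis. It was 0.17 in proNeu1 (highest of the other splits 0.145) and 0.113 in proNeu2 (0.0705), the highest of the 10 splits in both, as predicted. With 10 splits no share under 0.05 can be reached, so a shift along the axis is not shown there. Genes higher in control preNeu than in Ly6C- GMP went both ways. Ltf was at 34.28 CPM in sepsis against 936.5 in control proNeu1, and S100a8 at 841.8 against 494.1 in proNeu2. The correlation was 0.119 in Ly6C- GMP, where another split gave 0.134 and the test leaves the question open. In preNeu, with the axis drawn from Ly6C- GMP to proNeu2, it was -0.113, and 4 of 10 splits, the real one included, were as far from 0 (highest other 0.183), so the test leaves the question open there too.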
